A study of Sus scrofa with 9 samples.

How the data were processed

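Total RNA of the porcine ileal epithelial line IPI-2I was labelled from 5 µg per array and read on 1-colour Affymetrix porcine arrays, per the labels' protocols. The 9 arrays fall into uninfected cells at 0 h, cells infected with Salmonella Choleraesuis and sampled at 2 h, and infected cells sampled at 4 h, with 3 arrays each. The deposited values are log2 expression summaries per probe set, made with RMA under R 2.7.0 per the submitters' processing notes. RMA corrects background, normalizes by quantiles and summarises the probes of a set on the log2 scale. It compresses changes of dim probe sets, so fold changes near the bottom of the scale are understated. The notes do not say which arrays were normalized together, and no filter is given in the sources used here. The values have no counts or detection calls, so depth and background per probe set are unknown.

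The table holds 24123 probe sets. 124 control probe sets were left out of all tests, which leaves 23999. A platform annotation table names a single gene symbol for 10110 probe sets, of which 41 list that symbol for 2 gene identifiers, and several symbols for 157. 13732 probe sets are not listed there and are unnamed here. Symbols were checked through the gene identifiers of 9961 listed probe sets against a current RefSeq table, and 0 differed. For each of 6790 genes the probe set with the highest mean over all arrays was used, and 2271 genes had more than 1. For 1246 genes whose next brightest probe set lay above the median level, the changes of both correlated at r = 0.399 at 2 h, 0.477 at 4 h and 0.647 between 4 h and 2 h, across genes. When the brightest was called, the next went the same way in 81.8%, 80.9% and 90.0% of genes.

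Values were tested as deposited in R 4.3.3 with limma 3.58.1 (lmFit, eBayes) in 1 fit over all 9 arrays with group as the only factor. The contrasts were 2 h against uninfected, 4 h against uninfected and 4 h against 2 h, with a moderated F test over the 3 groups. P-values were two-sided and adjusted by Benjamini-Hochberg over the 23999 probe sets of each contrast, with a threshold of 0.05. The fit had 6 residual and 4.61 prior degrees of freedom. The contrast of 4 h with 2 h also tests the difference between the effects at both times.

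24 lists were fixed before the data were examined. They cover inflammatory cytokines and chemokines, NF-kappaB, immediate-early and MAPK feedback, interferon-stimulated genes, pattern recognition and inflammasome, apoptosis, cell junctions, cholesterol, unfolded protein response, heat shock, glycolysis and hypoxia, oxidative stress and metals, cell cycle, antimicrobial defence, antigen processing, autophagy and lysosome, the EGF family and wounds, ribosomal proteins and oxidative phosphorylation. The remaining lists hold markers of intestinal epithelium, leukocytes, fibroblasts and smooth muscle, and endothelium. 1 further list was tested and is not reported here. Each had at least 12 measured genes. Listed genes without a probe set naming them alone were not tested, so list results cover the measured members only. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists of a contrast. With the correlation estimated per list, no list was called in any contrast, with adjusted p from 0.493 at 2 h, 0.828 at 4 h and 0.852 between the times. The estimates were 0.489 for cholesterol, 0.263 for oxidative phosphorylation, 0.209 for immediate-early genes and 0.0627 for cell cycle, all above the preset.

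Genes were named by a rule set before the data were examined. For 2 h and for 4 h against uninfected it takes the 10 largest rises and 10 largest falls among genes past the threshold whose infected arrays all lie on one side of the uninfected ones. It takes 5 and 5 for 4 h against 2 h, up to 4 members of each list with the largest change past the threshold, and CXCL8, ACTB and GAPDH. This gave 105 genes.

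The alternatives were medians recentred, quantile normalization repeated, only the brighter probe sets, array weights, a prior with an intensity trend, the replicate number as a block, only the arrays compared, each array left out in turn, a 2-fold minimum, a threshold of 0.01, the mean of all probe sets of a gene, an estimated correlation, and fry. Added after seeing the data were only probe sets whose identifier has 1 as its second number, and a fit of 1 probe set per gene adjusted over those 6790 alone. For lists, all alternatives except the estimated correlation and fry kept the preset correlation of 0.01. Counts of alternatives that kept a list call therefore do not test that setting. No 2 arrays looked like copies of each other, with the SD of differences between arrays at 0.115 or more and correlations of 0.996 to 0.999 within groups.

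The code was tested on simulated data for the comparison of 4 h with uninfected, with 23999 probe sets drawn at the uninfected means and the measured spreads, and changes placed among brighter probe sets. It recovered 31 of 40 probe sets raised by 0.5 log2 units, 24 of 40 lowered by 0.5, 39 of 40 raised by 1, 39 of 40 lowered by 1 and 40 of 40 raised by 2. It called 5 of 23799 unchanged probe sets. Camera on 24 simulated lists called 1, the cholesterol list, which had been shifted by 0.3. The simulated genes were drawn independently, while the real cholesterol list had an estimated correlation of 0.489. The run therefore does not test false list calls among correlated genes.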

Results

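IPI-2I is an epithelial line from the ileum of an adult pig. Its transcripts were measured on Affymetrix porcine arrays before and after infection with Salmonella Choleraesuis, a serovar that causes systemic disease in pigs. Confluent cells met the bacteria for 1 h at a stated ratio of 1 to 10. They were then kept for 2 or 4 h with 50 µg/ml gentamicin, which kills bacteria outside the cells and spares those inside. 3 arrays each came from uninfected cells at 0 h, infected cells at 2 h and infected cells at 4 h, 9 in all. The design asks how the cells answer invasion over the first hours. All uninfected arrays are labelled 0 h, and gentamicin is stated for the infected arrays only. Infection, gentamicin, time in culture and handling therefore cannot be separated. The labels speak of triplicates without naming separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

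Among 23999 probe sets, 10110 carried 1 gene symbol and stood for 6790 genes. Array medians lay between 6.17 and 6.21 log2 units. The brightest probe sets of ACTB, cytoplasmic beta-actin, and GAPDH, a glycolytic enzyme, changed little. Both lay near the top of the scale, with means of 13.68 and 13.75 against array maxima of 14.03 to 14.20, so a rise would be hard to see. ACTB differed from uninfected cells by 0.08 ± 0.06 (SE) at 2 h and -0.01 at 4 h on the log2 scale, and GAPDH by 0.02 ± 0.05 at both times. None of these 4 differences passed the threshold (limma adjusted p between 0.443 and 0.945). A dimmer GAPDH probe set rose by 0.28 at 2 h (adjusted p = 0.0328) and 0.26 at 4 h (adjusted p = 0.0290). The first principal component held 41.8% of the variance and separated uninfected arrays (-26.4 to -10.5) from infected ones (3.94 to 16.0), with an overlap between the 2 h and 4 h arrays. The second held 17.7% and separated the 2 h arrays (-10.5 to -6.42) from the 4 h arrays (7.74 to 9.55), with uninfected arrays from -7.63 to 12.9. Uninfected replicate 1 lay at the far end of the first component and had the lowest array weight, 0.350.

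At 2 h most changes were small in size. CXCL2, a chemokine that attracts neutrophils, rose by 0.87 ± 0.13 (SE) on the log2 scale, 1.82-fold, from 10.31 ± 0.29 (SD, n = 3) to 11.18 ± 0.16 (limma adjusted p = 0.00511). LIF, a cytokine of the interleukin-6 family, rose by 0.50 ± 0.07 (adjusted p = 0.00441), EDN1, the endothelin-1 peptide, by 0.64 ± 0.11, and NFKBIA, an inhibitor of NF-kappaB that NF-kappaB itself induces, by 0.40 ± 0.09. TFRC, the transferrin receptor for iron uptake, fell by 0.79 ± 0.13 (adjusted p = 0.00763). MAPK8, a JNK kinase, fell by 0.75 and CASP8, the initiator caspase of death receptors, by 0.46. The brightest probe set of THBS1, a matrix glycoprotein, fell by 0.57. Its other probe sets disagreed. Dimmer ones fell by 0.91 and 0.90, while a nearly as bright probe set differed by 0.26 (limma adjusted p = 0.289) and another by -0.18 (adjusted p = 0.676). CXCL8, the gene of interleukin 8, whose protein the design names as a sign of cell activation, differed by only 0.11 ± 0.31 (adjusted p = 0.865).

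In that comparison 1860 probe sets passed an adjusted p of 0.05, 693 higher and 1167 lower, with a median absolute change of 0.36. 6 of them rose and 9 fell by at least 2-fold. By each gene's brightest probe set, with p adjusted over all 23999, 254 genes rose and 293 fell. The higher share was 37.3%, against 43.4% with arrays recentred on their medians and 45.9% with quantile normalization repeated. The largest rises among genes with separated arrays were PPP1CA, a catalytic subunit of protein phosphatase 1, at 1.06 ± 0.17, MANBAL at 1.03 ± 0.06 and AKAP1, a mitochondrial anchor of protein kinase A, at 1.02 ± 0.12. HNRNPL, a splicing regulator, rose by 0.86, BLOC1S1 by 0.78, the surface glycoprotein THY1 by 0.71, the lipid transfer protein PLTP by 0.69 and the myosin light chain MYL9 by 0.65. The largest fall was in CORO1C, an actin-binding coronin, at -0.94 ± 0.14. After it, TFRC and MAPK8 came MBOAT1 at -0.68, MIPOL1 at -0.67, the mitochondrial dehydrogenase GPD2 at -0.66, the ceramidase ASAH1 at -0.65, EBNA1BP2 at -0.63, the nucleoporin NUP50 at -0.62 and CBY1 at -0.62. Falls were more frequent among probe sets whose identifier has a second number above 1 (12.4% of 3402) than among those numbered 1 (3.61% of 20501). CORO1C, EBNA1BP2, NUP50, CBY1 and THBS1 were measured by such later-numbered probe sets. 1172 probe sets were called when only those numbered 1 were tested, a setting chosen after seeing the data. The count was 816, 601 and 701 without infected 2 h replicate 1, 2 or 3, 1204 and 1230 without uninfected replicate 1 or 2, and 1146 from the 6 arrays compared. 32 of the 62 named values past the threshold kept their call in every fit that left out 1 array. Those of NFKBIA and ASAH1 did not.

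Infected arrays also differed from uninfected ones in RNA controls. A 28S ribosomal RNA probe set was lower by 1.05 (pooled SD 0.26), 1 18S probe set lower by 0.71 (0.19) and another higher by 0.25 (0.14). The 3 prime minus 5 prime difference was higher by 0.07 for GAPDH (pooled SD 0.03) and 0.08 for EF1a (0.04) and lower by 0.07 for actin (0.06). The list changes against uninfected cells run over the same arrays as these differences. Among the gene lists, cell cycle and DNA replication was called lower at 2 h. 5 of its 32 measured genes fell and none rose, or 10 fell and 1 rose when adjusted over the list alone, with a median of -0.10. CCNA2, cyclin A2, fell by 0.46 ± 0.07, KIF20A, a mitotic kinesin, by 0.41 ± 0.07 and TYMS, thymidylate synthase, by 0.27. This was 1 of 2 list calls with camera at its preset correlation (adjusted p = 0.00251), and it was lost with an estimated correlation (adjusted p = 0.493), the highest value over 19 alternatives, of which 18 kept the call and the lowest gave 0.000673. The other call was mitochondrial oxidative phosphorylation, where 4 of 64 genes fell and none rose, also when adjusted over the list alone (median -0.07, adjusted p = 0.00255, and adjusted p = 0.861 with an estimated correlation). The complex I subunits NDUFS3 and NDUFS6 fell by 0.31 and 0.32. ATP5SL, which fell by 0.40, carries the list's prefix without being a subunit of the ATP synthase. The list was not called without uninfected replicate 2 (camera adjusted p = 0.0604) or with fry (adjusted p = 0.108). It passed in 16 of 19 alternatives, whose adjusted p ran from 4.18e-06 to 0.861.

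Inflammatory cytokines and chemokines were not called as a list at 2 h. LIF and CXCL2 were the 2 of its 29 genes that rose, 3 when adjusted over the list alone (median 0.07, camera adjusted p = 0.106). Its adjusted p over 19 alternatives ran from 0.0249 with fry to 0.578, and it passed the threshold in 3 of them. In the NF-kappaB list 2 genes rose and 1 fell of 14, with the same counts when adjusted over the list alone (adjusted p = 0.744). TNFRSF1A, a receptor of tumour necrosis factor, rose by 0.25, and MAP3K7, the kinase TAK1, fell by 0.29. Interferon-stimulated genes split, with 3 of 30 higher and 3 lower, 4 and 4 when adjusted over the list alone (adjusted p = 0.942). IRF7, an interferon regulator, rose by 0.43 ± 0.08, and DDX58, the RNA sensor RIG-I, fell by 0.26. Calls of MAP3K7, TNFRSF1A, TYMS, NDUFS3, NDUFS6, DDX58, JUP, CLDN7, FDPS, LBP and TOLLIP at 2 h were each lost in at least 1 fit without 1 array.

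At 4 h, LIF rose by 1.71 ± 0.07 (SE) on the log2 scale, 3.27-fold, from 4.99 ± 0.08 (SD, n = 3) to 6.70 ± 0.10 (limma adjusted p = 3.05e-06). DDIT4, a stress-induced inhibitor of mTORC1, rose by 1.78 ± 0.20, 3.42-fold (adjusted p = 0.000877), and VEGFA, the vascular endothelial growth factor, by 1.48 ± 0.10, 2.79-fold (adjusted p = 0.000153). CSF2, the cytokine GM-CSF, rose by 0.89 ± 0.11 (adjusted p = 0.00137), HMOX1, haem oxygenase 1, by 0.91 ± 0.07, INSIG1, which restrains sterol synthesis, by 1.02 ± 0.13, and MYC by 0.68 ± 0.07. EGR1, an immediate-early transcription factor, fell by 1.86 ± 0.36 (adjusted p = 0.00826), from a level that varied among uninfected arrays (7.68 ± 0.95, SD, n = 3). TFRC fell by 1.07 ± 0.13 (adjusted p = 0.00131), and CXCL8 differed by 0.46 ± 0.31 (adjusted p = 0.336).

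**Figure D1:**
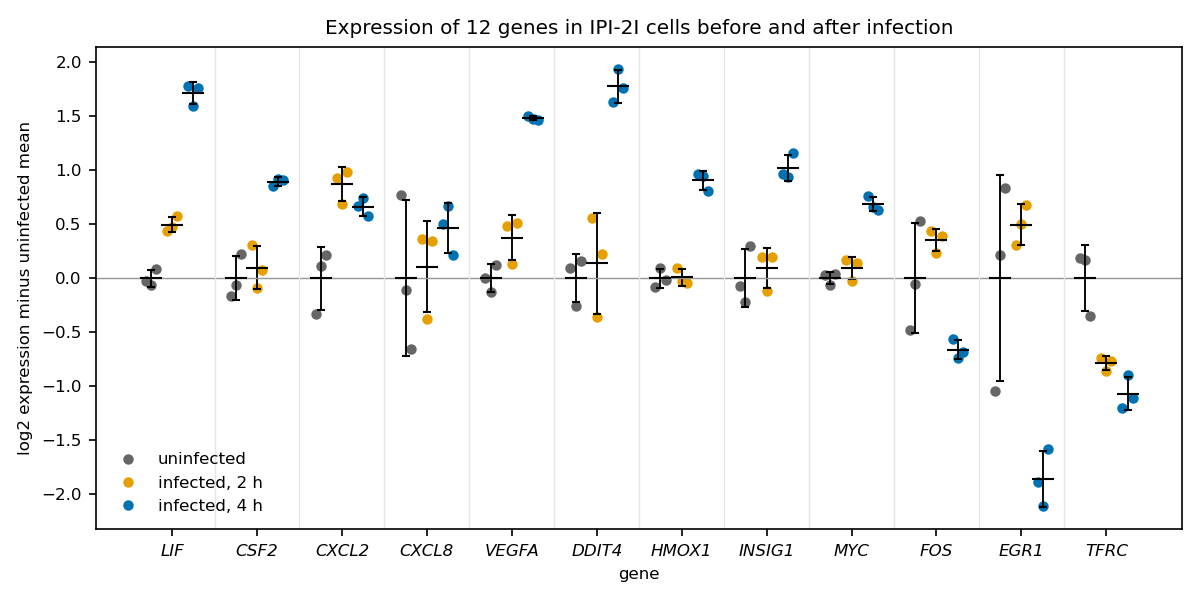
Log2 expression (y axis) of named genes (x axis) relative to the uninfected mean; points are single arrays and bars the mean and SD (n = 3) of uninfected, 2 h and 4 h arrays. LIF and DDIT4 stood 1.71 and 1.78 above the uninfected mean at 4 h, EGR1 stood at -1.86, and the uninfected arrays of CXCL8 spread over more than its changes.

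The number of probe sets past the threshold was 3658 at 4 h, 1754 higher and 1904 lower, with a median absolute change of 0.33. 15 rose and 13 fell by at least 2-fold. By gene, counted as at 2 h, 552 rose and 565 fell. ANKRD10 rose by 1.10 ± 0.09, and KMT5B, a histone methyltransferase, by 0.91 ± 0.11. PPP1CA at 1.08, AKAP1 at 1.04, MANBAL at 1.04 and HNRNPL at 0.93 stood about as high as at 2 h. Besides EGR1 and TFRC, the largest falls were in MIPOL1 at -0.92, CORO1C at -0.91, LOC595122 at -0.90, ITGA2, an integrin subunit for collagen, at -0.87, RND3 at -0.84, PPP1R3B, a glycogen-targeting phosphatase subunit, at -0.80, OIP5 at -0.80 and ID1, an inhibitor of transcription factors, at -0.78. Dimmer probe sets of RND3 differed by 0.13, 0.04 and -0.28 at 4 h without passing the threshold. Probe sets numbered above 1 fell more often (14.8%) than those numbered 1 (6.81%). The OIP5 and EGR1 values came from later-numbered probe sets, and an EGR1 probe set numbered 1 fell by 1.72. A dimmer EGR1 probe set numbered 1 differed by -1.15 without passing the threshold (limma adjusted p = 0.0615). The count was 2057 and 2230 without infected 4 h replicate 1 or 3, and 1966 from the 6 arrays compared. 73 of 99 named values past the threshold kept their call in every fit without 1 array.

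Inflammatory cytokines and chemokines had 4 of 29 genes higher and none lower, also when adjusted over the list alone (median 0.08). They were LIF, CSF2, CXCL2 at 0.66 ± 0.13 and TNF at 0.31 ± 0.09. Camera did not call the list (adjusted p = 0.122), while fry, which compares the list with no other genes, did (adjusted p = 0.00123). Over 19 alternatives its adjusted p ran from 0.00123 to 0.828, and fry was the only 1 past the threshold. NF-kappaB genes went both ways, 3 higher and 3 lower of 14, 5 and 4 when adjusted over the list alone (camera adjusted p = 0.949). NFKBIA rose by 0.41 and TNFRSF1A by 0.29, while TNFAIP8 fell by 0.54 and MAP3K7 by 0.33. Of 17 pattern recognition genes 3 rose, TICAM2 by 0.26, LBP by 0.24 and TOLLIP by 0.23, with the same count when adjusted over the list alone (camera adjusted p = 0.224, fry adjusted p = 0.0440). All 3 changes were small, and LBP lay near the bottom of the scale at 3.76. At 2 h TOLLIP and LBP were the 2 higher members (adjusted p = 0.466, 2 when adjusted over the list alone). Calls of TNF, NFKBIA, TICAM2 and TOLLIP at 4 h were each lost in at least 1 fit without 1 array.

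Camera at its preset correlation called the sterol genes higher at 4 h. 4 of 14 cholesterol synthesis and uptake genes rose and none fell, 8 and 1 when adjusted over the list alone, with a median of 0.19. INSIG1 rose by 1.02, SC5D, a late sterol desaturase, by 0.50 ± 0.10 and HMGCS1, an early enzyme of the mevalonate pathway, by 0.42 ± 0.12. FDPS differed by -0.21 (adjusted p = 0.108). The list passed camera (adjusted p = 0.0149), and not with an estimated correlation (adjusted p = 0.828) or with fry (adjusted p = 0.0724). It was not called without uninfected replicate 2 (adjusted p = 0.0628) or infected 4 h replicate 3 (adjusted p = 0.104). It passed in 15 of 19 alternatives, from an adjusted p of 0.00127 to 0.828. At 2 h its median was -0.06, with FDPS as the 1 lower member, also when adjusted over the list alone (adjusted p = 0.550). Mitochondrial oxidative phosphorylation was again called lower, with 9 of 64 genes down and none up, also when adjusted over the list alone (median -0.08, adjusted p = 0.00327, and adjusted p = 0.828 with an estimated correlation). 17 of 19 alternatives kept this call, the lowest at 9.26e-06. It was lost with the estimated correlation and with fry (fry adjusted p = 0.0613). NDUFAF1, an assembly factor of complex I, fell by 0.37 and NDUFS3 by 0.33. Cell cycle genes had 5 of 32 lower and 2 higher, 9 and 3 when adjusted over the list alone (camera adjusted p = 0.0891, fry adjusted p = 0.0440). HMMR, a spindle-associated hyaluronan receptor, fell by 0.52 and CCNA2 by 0.46.

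In the oxidative stress list 5 of 26 genes rose and 1 fell, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.363, fry adjusted p = 0.0440). HMOX1 rose by 0.91, GPX1, glutathione peroxidase 1, by 0.40 and GCLC, which makes glutathione's precursor, by 0.26, while PRDX1, a peroxiredoxin, fell by 0.32. Dimmer GCLC probe sets differed at 4 h by 0.09, -0.004, -0.09 and 0.03 without passing the threshold. Those at -0.09 and 0.03 had fallen past it at 2 h, by 0.29 and 0.26. At 2 h PRDX1, lower by 0.36, was the list's 1 changed gene by brightest probe sets, also when adjusted over the list alone (adjusted p = 0.942). Glycolysis and hypoxia genes had 2 of 27 higher and 3 lower, with the same counts when adjusted over the list alone (adjusted p = 0.423). DDIT4 and VEGFA rose, and SLC2A3, the glucose transporter GLUT3, fell by 0.56 together with TFRC. At 2 h 1 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.942). VEGFA had 4 probe sets, of which 2 rose at 4 h, the brightest by 1.48 and another by 0.62. Apoptosis genes had 1 of 25 higher and 3 lower, 2 and 3 when adjusted over the list alone (adjusted p = 0.723). PMAIP1, the BH3-only protein NOXA, fell by 0.67 and CASP8 by 0.61 ± 0.08. CASP8 alone fell at 2 h, also when adjusted over the list alone (adjusted p = 0.942). Unfolded protein response genes had 4 of 22 lower and 1 higher, with the same counts when adjusted over the list alone (adjusted p = 0.263). The chaperone partners DNAJB11 and PDIA3 fell by 0.40 and 0.29, and DDIT3, the transcription factor CHOP, rose by 0.43. At 2 h 3 fell and none rose, also when adjusted over the list alone (adjusted p = 0.194). Calls of HMGCS1, GCLC and DDIT3 at 4 h were each lost in at least 1 fit without 1 array.

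Among immediate-early and MAPK feedback genes at 4 h, 4 of 27 rose and 8 fell, 7 and 8 when adjusted over the list alone (median -0.07, camera adjusted p = 0.723). IER3, an early survival gene, rose by 0.71 ± 0.14 and MYC by 0.68, while EGR1 fell by 1.86 and FOS by 0.66 ± 0.19. At 2 h 1 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.106). Interferon-stimulated genes had 2 of 30 higher and 7 lower, 4 and 7 when adjusted over the list alone (adjusted p = 0.723). IRF7 rose by 0.51 and PML by 0.40, and DDX58 fell by 0.36. Cell junction genes had 1 of 19 higher and 1 lower at each time, also when adjusted over the list alone (adjusted p = 0.942 at 2 h and 0.897 at 4 h). JUP, plakoglobin, rose by 0.60 at 2 h and 0.52 at 4 h, and the claudin CLDN7 fell by 0.25 and 0.29. Calls of FOS and JUP at 4 h were each lost in at least 1 fit without 1 array.

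**Figure D2:**
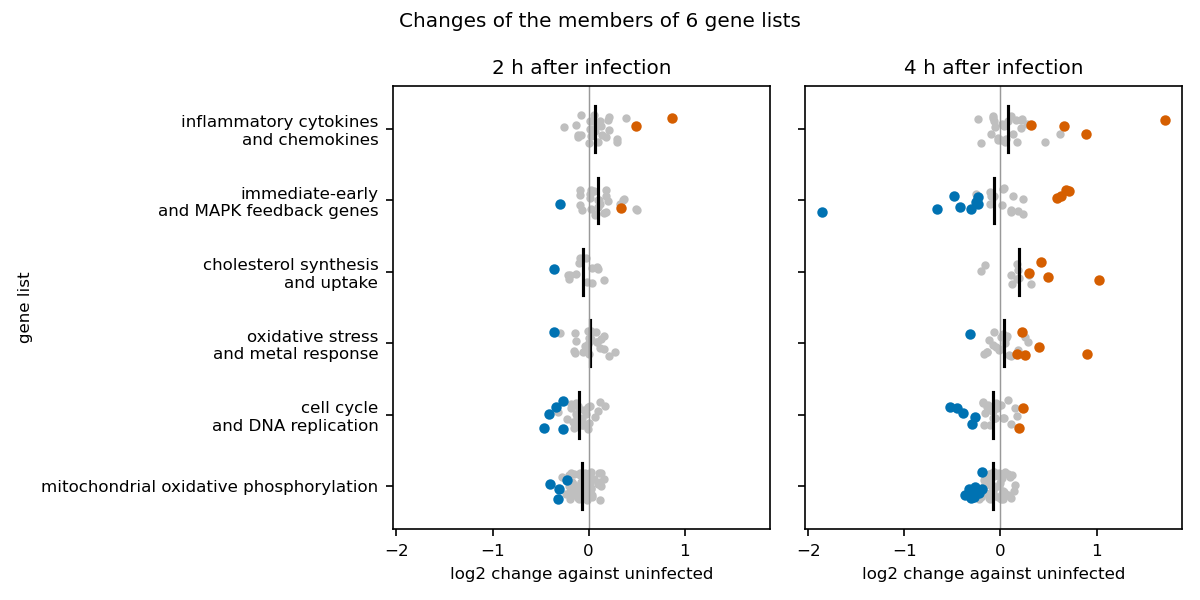
Log2 change against uninfected cells (x axis) of each member of selected gene lists (y axis) at 2 h and 4 h; red and blue points are genes past the adjusted p threshold that rose or fell, grey points did not pass it, and black bars are medians. The cholesterol list shifted from a median of -0.06 at 2 h to 0.19 at 4 h, and no member of the oxidative phosphorylation list rose past the threshold at either time.

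**Figure D3:**
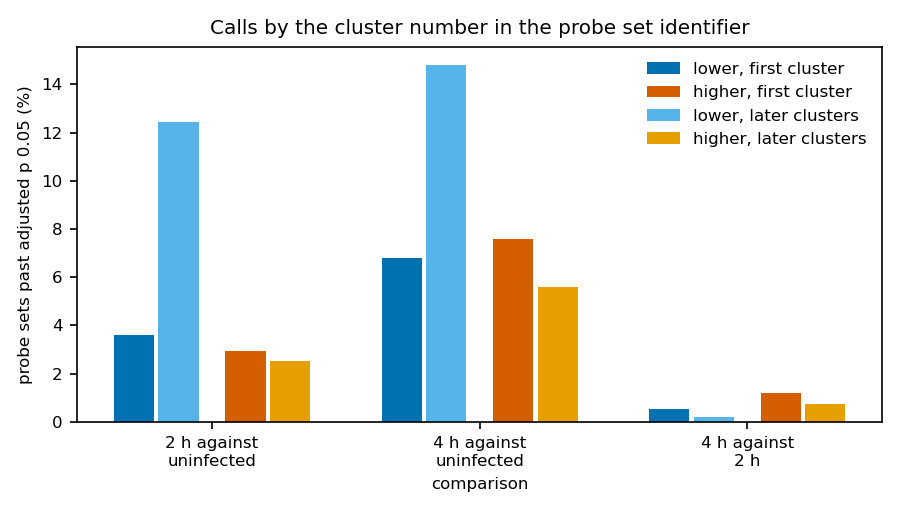
Share of probe sets past the adjusted p threshold (y axis, %) in each comparison (x axis); paired bars are probe sets whose identifier has a second number of 1 (first cluster) or above 1 (later clusters), split into lower and higher. At 2 h 12.4% of later and 3.61% of first probe sets fell, and at 4 h 14.8% and 6.81%.

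Between 2 h and 4 h, DDIT4 rose by 1.64 ± 0.20 (SE) on the log2 scale (n = 3 and 3, limma adjusted p = 0.00401), ANKRD10 by 1.26 ± 0.09, LIF by 1.21 ± 0.07 (adjusted p = 0.000106), VEGFA by 1.10 ± 0.10 and KMT5B by 1.03 ± 0.11. INSIG1 rose by 0.93, HMOX1 by 0.90 and CSF2 by 0.80. EGR1 fell by 2.35 ± 0.36 (adjusted p = 0.0119), FOS by 1.01 ± 0.19, CCNG2, a cyclin linked to cell cycle exit, by 0.85 ± 0.09, PPP1R3B by 0.76 and CCDC71 by 0.74. EGR1 and FOS had stood 0.50 and 0.35 above uninfected cells at 2 h without passing the threshold.

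381 probe sets passed the threshold in this comparison, 266 higher and 115 lower, and 13 rose and 5 fell by at least 2-fold. The excess of falls among later-numbered probe sets was absent here (0.176% against 0.532%). The count was 131, 113 and 95 without infected 2 h replicate 1, 2 or 3, 193, 128 and 129 without infected 4 h replicate 1, 2 or 3, 595 without uninfected replicate 1 and 923 with array weights. 13 of 21 named values kept their call in every fit without 1 array. FOS lost its call in 6 such fits, GPX1 in 5 and EGR1 in 3.

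Of 14 cholesterol synthesis and uptake genes 2 were higher, none lower and 12 not past the threshold, or 9 higher and 0 lower when adjusted over the list alone. Camera called the list higher at 4 h than at 2 h (median 0.31, adjusted p = 9.47e-09). With an estimated correlation its adjusted p was 0.852, and with fry 0.0710, the 2 of 19 alternatives that lost the call, the lowest being 1.39e-11. Of 27 immediate-early genes 5 were lower, 2 higher and 20 not past the threshold, or 9 lower and 5 higher when adjusted over the list alone. Camera called the list lower (median -0.11, adjusted p = 0.0161). That call was lost with an estimated correlation (adjusted p = 0.852), with fry (0.438), and without infected 2 h replicate 1 (0.0505) or 3 (0.0640). 14 of 19 alternatives kept it, with an adjusted p from 0.00217 to 0.852 over all of them. MYC went against the list and rose by 0.59. The oxidative stress list was not called (adjusted p = 0.0951), with HMOX1 and GPX1 as its 2 higher genes, also when adjusted over the list alone. Inflammatory cytokines and chemokines had LIF and CSF2 higher, also when adjusted over the list alone (adjusted p = 0.670). No further list passed the threshold (lowest adjusted p = 0.514).

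Most of what changed at 2 h was still changed at 4 h. 1490 probe sets, 80.1% of those called at 2 h, were called in the same direction at both times, 554 higher and 936 lower, and 3 in opposite directions. Independent lists would share 50.6 higher and 92.6 lower. The fold changes of the 2 comparisons correlated across probe sets (r = 0.763), which are not independent replicates. Both comparisons use the same uninfected arrays. 100 simulated series with no change were built from the residuals within groups. Their median r was 0.543 and the highest 0.920, so the observed r lies within that range. The highest number of shared calls was 0. Series without any change leave few or no calls to share, so this 0 does not measure how far the shared arrays raise the overlap. The median covariance was 0.00426, against an observed covariance of 0.0269, a difference of 0.0226. Part of the excess of shared calls may come from the shared arrays, which are too few to split. The shared count was 704, 545 and 627 without infected 2 h replicate 1, 2 or 3. By brightest probe sets, MANBAL, PPP1CA, AKAP1, HNRNPL, BLOC1S1 and MYL9 were higher, and TFRC, CORO1C, MIPOL1, GPD2 and THBS1 lower, at both times. Among the other THBS1 probe sets some fell too and others passed the threshold at neither time.

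A moderated F test over the 3 groups called 3154 probe sets. It called 1944 without uninfected replicate 2, 2062, 2031 and 1927 without infected 2 h replicate 1, 2 or 3, and 1950 without infected 4 h replicate 3.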

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

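The tests of 3 prime bias, of lower mRNA and of CXCL8 were set down after the result was seen. The criteria for lower mRNA and for 3 prime bias were revised once their values were known, which left both explanations open. The other tests were set before their values. The genes and lists below are those whose change against uninfected cells differed between 2 h and 4 h by the direct test of 4 h against 2 h (limma or camera adjusted p under the threshold). LIF was higher at 4 h than at 2 h by 1.21 on the log2 scale, VEGFA by 1.10, CSF2 by 0.80 and the protease PLAU by 0.44. Also higher at 4 h than at 2 h were DDIT4 by 1.64, ANKRD10 by 1.26, KMT5B by 1.03, INSIG1 by 0.93, HMOX1 by 0.90, MYC by 0.59, the ribosomal protein gene RPL37 by 0.52, the epithelial transcription factor ELF3 by 0.41 and GPX1 by 0.31. The genes that were lower at 4 h than at 2 h were EGR1 (-2.35), FOS (-1.01), CCNG2 (-0.85), PPP1R3B (-0.76), CCDC71 (-0.74), PMAIP1 (-0.52), RND3 (-0.48) and SLC2A3 (-0.41). Of the 21 genes, 13 kept this call in every fit without 1 array. PLAU, ELF3, GPX1, RND3 and SLC2A3 lost it in 5 of 9 such fits, PMAIP1 and FOS in 6 and EGR1 in 3. The median member of the cholesterol list differed by 0.31 and that of the immediate-early list by -0.11. Both list calls were lost with an estimated correlation (adjusted p = 0.852 for each) and with fry (0.0710 and 0.438).

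Falls against uninfected cells were concentrated in probe sets whose identifier has a second number above 1, and this pattern was not a planned comparison. Uninfected replicate 1 alone is argued against, since without it the share of falls stayed 2.22 times as high in later-numbered probe sets. Lower mRNA of the same genes stays open. Among 262 genes with such a fallen probe set at 4 h, the brightest probe set had a median of -0.0883. Its 95% bootstrap interval of -0.10 to -0.07 resamples genes of the same arrays, so it does not measure the spread between arrays. Of the 262, 200 lay below 0 and 52 were called lower, as were 565 of all 6790 genes. The fallen probe sets, whose -0.40 is inflated by their selection, cannot serve as the measure of size. Stronger 3 prime bias in the infected arrays stays open too. The 3 prime minus 5 prime difference was higher than in uninfected arrays for 2 of 3 control genes, GAPDH by 0.07 (pooled SD 0.03) and EF1a by 0.08 (0.04). For actin it was lower by less than 2 standard errors (-0.07, pooled SD 0.06).

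CXCL8 did not pass the threshold although interleukin 8 protein is named in the design. Its probe set lay at the 78.4th percentile of all levels, which argues against a dim or saturated measurement. The uninfected arrays read 9.03, 8.14 and 7.60. Without uninfected replicate 1 the change at 4 h was 0.85 ± 0.24 (SE) with an adjusted p of 0.0473, while over all 18 alternatives the adjusted p ran from 0.0473 to 0.767, so a high CXCL8 level in that array is a candidate explanation, found on the same data. Why that array read high was not tested, and at 2 h no alternative passed the threshold (lowest adjusted p 0.284).

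Changes at 2 h and 4 h were largely shared. The covariance of 0.0269 lay above the highest of 100 unchanged series (0.0127), which argues against the spread between arrays of a group as the whole source. Those series shuffled residuals within groups, so they cannot hold an offset common to the uninfected arrays, which stays open. They also mixed residuals of uninfected arrays (SD 0.098 to 0.128) with those of infected ones (0.070 to 0.093), so they may understate the noise of the uninfected arrays. Infection, gentamicin, time in culture and handling remain open as sources of the shared changes, since each separates the same arrays.

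For the count of 2 h against uninfected, 1 of the 10 splits of the 6 arrays reached 1860, the real one, and the highest other split gave 0. At 4 h the real count was 3658 and the highest other 0, and for 4 h against 2 h 381 and 0. 10 splits are too few for a share under 0.05. Over 3 groups, 1 of 100 splits reached 3154, the real one, which argues against a chance division of the arrays. The highest other split gave 1469, and it kept the uninfected arrays together.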

How the results depend on the processing

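182 of 231 named values passed the threshold, and none of these changed direction under any alternative. The genes were chosen by these same values, many with separated arrays, whose direction cannot flip when arrays are left out or reweighted. The lack of reversals is therefore largely set by the choice and is no measure of stability. Of the 182, 1 call was lost with arrays recentred, 9 with quantile normalization repeated, 10 with array weights, 2 with an intensity trend and 17 with the mean of all probe sets of a gene. Leaving out 1 array lost between 10 and 49, and the 6 arrays compared lost 40. With identifiers numbered 1 only, a setting chosen after seeing the data like that of 1 probe set per gene, 3 of 150 were lost. The replicate number as a block lost 18 and called 1517 probe sets at 2 h, 3401 at 4 h, 346 between the times, 2769 by F test and 1226 shared. Replicate numbers were not shown to pair the arrays, since 3 of 9 same-number pairs had a residual correlation above 0.1 (-0.06 to 0.16), while 7 of 9 arrays correlated best with an array of their own number. RMA values carry no background estimate, so signal over background is unknown.

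At 2 h, 1860 probe sets became 1146 with the 6 arrays compared and 1172 with identifiers numbered 1, by fewer arrays or probe sets. They became 753 in a fit of 1 probe set per gene, adjusted over those 6790 alone, 15 at 2-fold and 468 at an adjusted p of 0.01, by construction. At 4 h, 3658 became 1966 with the 6 arrays compared, 1401 in the fit of 1 probe set per gene, 28 at 2-fold and 1248 at 0.01. Between the times, 381 became 923 with array weights, for which the cause was not tested, 165 in the fit of 1 probe set per gene, 18 at 2-fold and 85 at 0.01. List calls, 2 in each comparison, became 5 at 2 h with the mean of all probe sets and 0 with an estimated correlation. They became 0 and, with fry, 4 at 4 h, and between the times 1 among the brighter probe sets, 0 with an estimated correlation and 0 with fry. The cause was not tested.

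Leaving out 1 array gave 601 to 2607 probe sets at 2 h, 2057 to 4129 at 4 h, 95 to 595 between the times, 1927 to 3473 by F test and 545 to 2097 shared. List calls ran from 1 to 4 at 2 h, 1 to 2 at 4 h and 1 to 2 between the times. Fewer arrays lower such counts by construction, and the cause of the rises was not tested.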

Other observations

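Of 31 antimicrobial and mucosal defence genes none changed at 2 h (camera adjusted p = 0.942), and 2 rose and 1 fell at 4 h, with the same counts when adjusted over the list alone (adjusted p = 0.423). PLAU, the urokinase protease, rose by 0.63 and CFB, complement factor B, by 0.30, while SLC11A2, an iron transporter, fell by 0.49. Of 17 EGF family and wound genes 1 rose and 2 fell at 2 h, also when adjusted over the list alone (adjusted p = 0.942), and 3 rose and 2 fell at 4 h, 5 and 4 when adjusted over the list alone (adjusted p = 0.723). By their brightest probe sets, TGFB1, a growth inhibitory cytokine, rose by 0.33 and 0.40, against falls of ITGA2 and THBS1. Of 26 antigen processing genes 1 fell at 2 h, also when adjusted over the list alone (adjusted p = 0.642), and 2 at 4 h, 1 when adjusted over the list alone (adjusted p = 0.723). The proteasome activators PSME3 and PSME2 fell by 0.39 and 0.19 at 4 h. Of 31 autophagy and lysosome genes 1 fell at 2 h, also when adjusted over the list alone (adjusted p = 0.942), and 2 rose and 2 fell at 4 h, also when adjusted over the list alone (adjusted p = 0.772). ATP6V1A, a proton pump subunit, fell by 0.42 and 0.45 and ATG7, an autophagy enzyme, by 0.22 at 4 h, and GABARAP and ATP6V0C rose by 0.25 and 0.17 at 4 h. Leaving out 1 array lost the 4 h calls of GABARAP and ATP6V0C in 8 of 9 fits, of ATG7 and PSME2 in 7, of CFB in 4 and of PSME3 in 1. It lost the 2 h calls of TGFB1 in 8, of ITGA2 in 6 and of ATP6V1A in 3.

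Ribosomal protein genes had 3 of 64 lower at 2 h, also when adjusted over the list alone (camera adjusted p = 0.194, fry adjusted p = 0.0379). At 4 h they had 4 lower and 1 higher, 2 and 1 when adjusted over the list alone (camera adjusted p = 0.340). RPL37 rose by 0.66 at 4 h, and RPS9 and RPS24 fell by 0.26 and 0.22 at 2 h and by 0.25 and 0.23 at 4 h. RPS19BP1, which fell by 0.28 and 0.25, binds a ribosomal protein and is none itself. Heat shock genes had 1 of 20 higher at 2 h, also when adjusted over the list alone (adjusted p = 0.942), and 1 higher and 1 lower at 4 h, 0 and 1 when adjusted over the list alone (adjusted p = 0.423). BAG3, a co-chaperone, rose by 0.31 and 0.24, and HSPH1, a chaperone, fell by 0.45 at 4 h. The caspases CASP2 and CASP6 changed by 0.25 and -0.20 at 4 h, DNAJC3, a chaperone partner, fell by 0.24 and 0.26, and TRIM26, an interferon-stimulated ligase, rose by 0.33 at 2 h. Leaving out 1 array lost the calls of CASP6 in 9 of 9 fits, CASP2 in 8, BAG3 in 5 at 2 h and 7 at 4 h, RPS19BP1 in 5 and 7, DNAJC3 in 6 and 3, RPS24 in 6 and 1, RPS9 in 3 at 2 h and TRIM26 in 6.

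Marker lists showed no call at either time. In uninfected cells the epithelial median lay below the array medians of 6.19 and below that of fibroblast and smooth muscle markers. These levels are no shares of cells and do not by themselves show an epithelial identity. Epithelial markers had a median level of 5.78 in uninfected cells, 5.89 at 2 h and 5.85 at 4 h, with 1 of 14 lower at 2 h, also when adjusted over the list alone (adjusted p = 0.744), and 1 higher and 1 lower at 4 h, 2 and 1 when adjusted over the list alone (adjusted p = 0.373). ELF3 rose by 0.49 at 4 h. Leukocyte markers lay at 4.58, 4.62 and 4.63, with 1 of 20 higher at each time and none when adjusted over the list alone (adjusted p = 0.194 and 0.224). These were SPI1, by 0.33 at 2 h, and CD3G, by 0.57 at 4 h, whose calls were lost in 7 and 2 of 9 fits without 1 array. Fibroblast and smooth muscle markers lay at 6.98, 7.11 and 7.11, with 1 of 16 higher and 1 lower at each time, also when adjusted over the list alone (adjusted p = 0.550 and 0.723). THY1 was higher and COL1A2, a collagen chain, lower by 0.37 and 0.41, the first call being lost in 2 of 9 fits without 1 array. Endothelial markers lay at 4.97, 5.03 and 5.08, with 1 of 12 higher and 1 lower at each time, 1 and 2 at 2 h and 1 and 1 at 4 h when adjusted over the list alone (adjusted p = 0.744 and 0.372). ENG, endoglin, rose by 0.54 and 0.50 and FLT1, a VEGF receptor, fell by 0.50 and 0.45.

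Ribosomal RNA control probe sets were lower in infected than in uninfected arrays, 28S by 1.05 (pooled SD 0.26) and 0.42 (0.17) and 18S by 0.71 (0.19) in 1 probe set, while another 18S probe set was higher by 0.25 (0.14). The labelling and hybridization controls BioB, CreX and bioC differed by -0.11, 0.02 and -0.04.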
